A study of Mus musculus with 24 samples.

How the data were processed

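Messenger RNA of 24 mouse macrophage cultures was sequenced, 3 libraries in each of 8 groups of cytokine (M-CSF or GM-CSF), genotype (LysM-Cre-positive or Cre-negative cells with loxP-flanked Hif1a) and stimulus (none or heat-fixed S. aureus). Per the labels' protocols, marrow cells were cultured with the cytokine, sorted by surface markers and left to adhere before stimulation, and stranded libraries were made from polyadenylated RNA. Per the submitters' processing notes, reads were aligned to mm10, and bcl2fastq, STAR 2.5.2b, FastQC and DESeq2 are named without their roles. The counter and the gene annotation are not given in the sources used here, so counts of paralogs, near-identical copies and overlapping genes are uncertain.

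The deposited count table holds raw counts per gene and library, per the file headers, in 43346 gene entries, and every value is a whole number. A deposited table of normalized signal holds 22017 genes, and each library's column equals the raw counts divided by 1 factor, as the files show. A deposited table of the authors compares GM-CSF with M-CSF in WT control cells and gives, per the file headers, a log2 fold change with its standard error, a test score, a p-value and an adjusted p-value for 9336 genes. The largest adjusted p listed is 0.0499, so genes above that are absent from it. Fold changes, errors and tests in the text were computed from the raw counts, and the deposited comparison served only for the sentence that sets it beside the fit.

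Samples were grouped by their labels, and no library was left out. Library totals ran from 25301386 to 40026472 counts, and the 10 most abundant genes took 8.9 to 13.3% of the counts. Genes were kept by the edgeR function filterByExpr with the groups as its argument, which left 14043. Libraries were scaled by TMM (factors 0.793 to 1.19), and 1 edgeR quasi-likelihood model (edgeR 4.0.16, R 4.3.3, robust fit) with 8 group means and no covariate was fitted to all 24 libraries. Contrasts gave the comparisons of cytokines, stimulus and genotype, the mean genotype effect over 4 conditions, and the differences between effects. The p-values were adjusted over the genes tested by Benjamini and Hochberg, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the root of the F statistic. Expression is in CPM scaled by TMM. Gene groups were 24 gene lists and 9 marker lists, tested where at least 5 members were measured with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Members called were counted over all genes tested and adjusted over the list alone.

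The lists, the comparisons, their tests, the alternatives and the rule for naming genes were chosen before the data were examined. The relations with exon length and GC content, the counts of ribosomal protein genes and some tests of the closing parts, named there, were not. By that rule the text names Hif1a and Lyz2 for every genotype comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 10 CPM and groups that do not overlap (predicted genes and receptor segments left out), up to 6 list members with the smallest adjusted p and members that move against their list, the most abundant members of marker lists, and list members named in another comparison. Where no gene passed, the 5 with the smallest p were named. Some genes open to naming by the rule are not reported here. Csf1r, Ltf, Mpo, Gm10116 and 5031414D18Rik were named after their values were seen. Groups with 0 counts were given a floor of 3 counts over the group for fold bounds, and ratios against 1 to 3 counts have an exact 95% counting interval. Coordinates are those of GRCm38 in GENCODE M21.

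Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test (DESeq2 1.42.0), a fit of the compared groups alone, the replicate number as a block, the replicate number within genotype as a block, and a fit without each library in turn. For the KO against WT comparisons the block within genotype could not be fitted, since it takes up the genotype. The labels do not say what a replicate number shares. In GM-CSF KO cells the deviations from the group means of control and S. aureus libraries of the same number correlated at 0.135, 0.348 and 0.348, so the numbers pair these libraries by the data, not by the labels. In the 9 other comparisons of 2 groups at least 1 such correlation was under 0.1. The fit was tested on counts simulated for all 24 libraries from the fitted means and spreads. The M-CSF KO and WT control groups were made alike except for 200 genes with known changes, and 13963 genes were tested. The fit called 52 of 67 genes changed 1.5-fold (77.6%), 65 of 67 changed 2-fold (97.0%) and 66 of 66 changed 4-fold, with 8 false calls among 191. The simulated libraries were independent, so this says nothing about paired libraries. Each gene was given the same spread in all groups. The simulation therefore says nothing about false calls where the spread differs between groups.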

Results

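Messenger RNA was sequenced from 24 cultures of mouse bone marrow-derived macrophages. Bone marrow of C57BL/6 mice with loxP-flanked Hif1a alleles was grown in M-CSF or GM-CSF, growth factors that drive marrow cells toward macrophages. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1. Cells from mice that carry LysM-Cre, a recombinase inserted into the Lyz2 gene and active in myeloid cells, are called KO here, and Cre-negative cells WT. M-CSF cells had been sorted as positive for CD11b and F4/80, and GM-CSF cells as CD115-high and MHCII-negative. After a night of adherence the cells were left untreated (control) or were given heat-fixed Staphylococcus aureus (S. aureus). Each of the 8 groups of cytokine, genotype and stimulus held 3 libraries. Total counts ran from 25301386 to 40026472 per library, and 14043 genes passed the filter on low counts. Expression is given as CPM (counts scaled to a common library total, mean ± SD of 3 libraries) and differences as log2 fold changes ± SE. Gene symbols are those of the deposited tables, so Irg1 stands for Acod1, Nov for Ccn3 and Emr1 for Adgre1. "Rose", "fell", "higher" and "lower" are used of genes with an adjusted p under 0.05 by edgeR. In the comparisons of 2 groups all 3 libraries of one group lay beyond all 3 of the other for each gene named as such.

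The first principal component held 64.6% of the variance and parted the M-CSF from the GM-CSF libraries. The second held 22.9% and parted stimulated from control libraries, and the third held 5.44%.

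**Figure D1:**
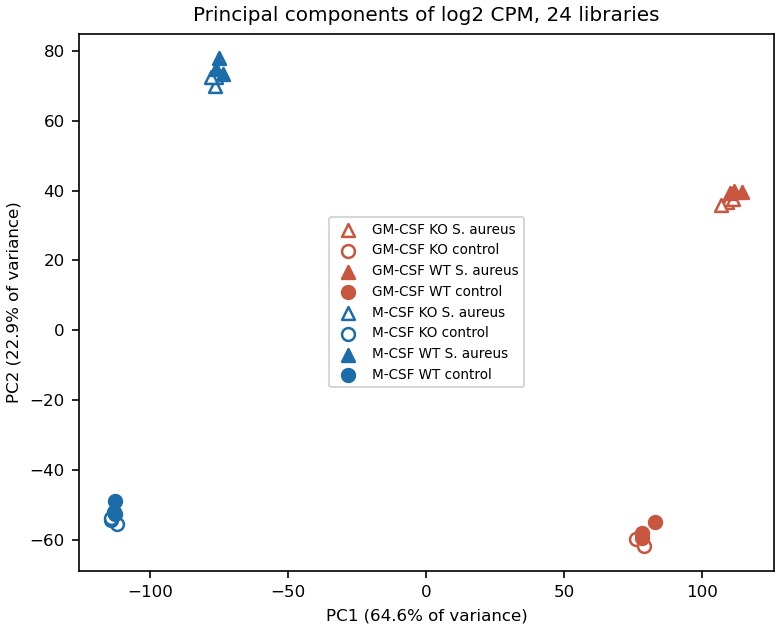
Principal components 1 and 2 of log2 CPM, with the percentage of variance on each axis; each point is 1 of 24 libraries, blue for M-CSF and red for GM-CSF, filled for WT and open for KO, with the marker shape giving the stimulus. Component 1 (64.6% of the variance) separates the cytokines and component 2 (22.9%) separates S. aureus from control.

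The targeted gene and the Cre locus were read first, as a check of the labels. The Hif1a total (chromosome 12, 73901375 to 73947530, GRCm38) was not lower in KO libraries. In M-CSF control cells it averaged 103 ± 5.30 CPM in WT and 136 ± 4.13 CPM in KO, and after S. aureus 292 ± 4.81 and 311 ± 3.87 CPM. In GM-CSF control cells it averaged 164 ± 17.1 CPM in WT and 233 ± 10.7 CPM in KO, and after S. aureus 268 ± 11.7 and 344 ± 32.5 CPM. All 3 KO libraries lay above all 3 WT libraries in each of the 4 conditions, from 134 to 141 against 99 to 109 CPM in M-CSF control, 306 to 314 against 287 to 296 in M-CSF S. aureus, 226 to 246 against 148 to 182 in GM-CSF control and 306 to 366 against 256 to 280 in GM-CSF S. aureus. The difference passed the test in M-CSF control (0.41 ± 0.08, adjusted p = 0.00805), in GM-CSF control (0.51 ± 0.08, adjusted p = 0.00193) and as the mean of the 4 conditions (0.34 ± 0.04, adjusted p = 6.18e-06). After S. aureus it was 0.09 in M-CSF (adjusted p = 0.572) and 0.36 in GM-CSF cells (adjusted p = 0.0735). Counts per gene do not show which exons the reads came from, and the deleted part is not given by the labels, so this gene's total cannot check the deletion. Lyz2 (chromosome 10, 117277331 to 117282321), which encodes lysozyme M and carries the Cre insertion, was lower in all 3 KO than in all 3 WT libraries of each condition. It stood at 49.8% of the WT mean in M-CSF control (-1.01 ± 0.14), 63.0% in M-CSF S. aureus (-0.67 ± 0.14), 45.8% in GM-CSF control (-1.13 ± 0.14) and 59.3% in GM-CSF S. aureus (-0.75 ± 0.14), with a mean difference of -0.89 ± 0.07 (adjusted p = 1.44e-09). Its near-identical neighbour Lyz1 was higher in KO by 0.95 ± 0.12 as the mean of the 4 conditions, and how the authors' counter shared reads between such copies is not given in the sources used here.

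Unstimulated WT cells were compared to ask how the baseline of the macrophages differs between the growth factors. The sort gates differed too, so gate and growth factor cannot be told apart in any comparison between the cytokines. This holds for differences of responses and of KO effects as well. GM-CSF cells expressed the chemokines Ccl17 and Ccl22, which bind the receptor CCR4, at 1774 ± 544 and 930.0 ± 47.5 CPM. In M-CSF cells Ccl17 had 0 counts, so it was at least 62600-fold higher in GM-CSF cells, and Ccl22 averaged 0.139 CPM. GM-CSF cells were also higher in Clec4n, the receptor Dectin-2 for fungal and bacterial sugars (9.56 ± 0.20), and in the macrophage elastase Mmp12, which averaged 16600 ± 1140 CPM (4.69 ± 0.18). M-CSF cells were higher in the folate receptor Folr2, at 1116 ± 111 CPM against 0.0337 in GM-CSF cells, in the lipid carrier Apoe (-8.46 ± 0.24) and in the scavenger protein Cd5l (-10.30 ± 0.32). Among the other genes with the largest changes, Plet1 (13.53) and the protease inhibitor Serpinb2 (12.23) rose, while Hmga2 (-11.02) and the collagen gene Col18a1 (-10.50) were lower in GM-CSF cells. The soluble pattern receptor Ptx3 was at least 9250-fold and the matrix protein Nov at least 5260-fold higher, both with 0 counts in M-CSF cells. Nptx1 was at least 4190-fold and the cytokine Il10 at least 520-fold lower, both with 0 counts in GM-CSF cells. These bounds take 3 counts over the group as the floor, and floors and intervals here cover counting error only.

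MHC class II genes were a group in which GM-CSF cells were higher: 13 of 14 measured members rose, among them H2-Aa (1458 ± 233 against 46.6 ± 10.4 CPM), the invariant chain Cd74 (3.92) and the class II transactivator Ciita (9.13), and the protease gene Ctss fell (-0.56; set adjusted p = 6e-21). Per the labels these cells had been sorted as MHCII-negative. All 10 measured dendritic cell markers were higher, including Ccr7 (9.68), Fscn1 (8.76) and Kmo (7.91; set adjusted p = 7.41e-18). So were all 8 monocyte and progenitor markers, such as Ly6c2 (9.26) and Ccr2 (2.86; set adjusted p = 8.46e-07), and 12 of 13 neutrophil markers, led in level by Mmp8 at 954 CPM, S100a8 at 122 CPM and S100a9 at 104 CPM (set adjusted p = 0.000374; adjusted p = 0.110 with an estimated correlation). Genes of alternative activation were higher in 13 of 14 cases, among them the lectin Mgl2 (9.75), the transcription factor Irf4 (5.54) and Arg1 (2.90), with Tgm2 lower (-1.53; set adjusted p = 1.28e-12). Of 26 genes of M-CSF and tissue-resident macrophages, 19 were lower and 3 higher in GM-CSF cells. The complement gene C1qb (-3.54), the transcription factor Maf (-3.25), the bridging ligand Gas6 (-6.25) and F4/80 (Emr1, -2.45) were lower, and the integrin Itgam (CD11b, 2.36), the phagocytic receptor Mertk (1.17) and Tgfbr1 (0.60) were higher (set adjusted p = 1.81e-16). Csf1r, which encodes CD115 and was named for the sort gate after its value was seen, was 891 ± 31.7 CPM in M-CSF and 739 ± 99.9 CPM in GM-CSF cells (adjusted p = 0.0888). Of the genes of alveolar macrophages and PPAR-gamma, 11 of 17 rose, such as the chitinase-like Chil3 (10.78) and Cd11c (Itgax, 5.68), while 4 fell, among them Pparg itself (-3.10; set adjusted p = 1.32e-06).

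The resting inflammatory state differed as well. In GM-CSF cells 22 of 28 genes of NF-kB feedback and signalling were higher, among them the signalling scaffold Malt1 (4.25) and the cytokine signal inhibitor Socs3 (6.38), and 5 were lower, including the MAP kinase phosphatase Dusp1 (-2.37; set adjusted p = 5.02e-09). Inflammatory cytokines were higher in 16 of 21 cases, such as Il1a (9.66), Il1b (7.23) and Csf1 (5.70), and lower in 2, Il10 and Il18 (-1.80; set adjusted p = 1.23e-05). Chemokines were higher in 12 of 21 cases, with Cxcl3 at 11.81, and lower in 4, with Cxcl14 at -5.06 (set adjusted p = 3.22e-06). Antimicrobial genes were higher in 17 of 22 cases, such as Irg1, the itaconate-producing enzyme (7.53), and the cystine carrier Slc7a11 (9.09; set adjusted p = 5.02e-09). Osteoclast markers were higher in 5 of 6 cases, such as Dcstamp (4.68; set adjusted p = 0.000335). Genes of the type I interferon response went the other way: 25 of 31 were lower in GM-CSF cells, among them Ifit3 (-5.03) and Irf7 (-4.00), and 3, the guanylate-binding Gbp2, Gbp3 and Gbp5, were higher (set adjusted p = 2.4e-07; adjusted p = 0.417 with an estimated correlation). For these lists the counts adjusted over the list alone were the same, except 4 higher for the tissue-resident genes, 18 for the antimicrobial genes, 13 for the neutrophil markers and 6 for the osteoclast markers. In all, 9190 genes differed, 5210 higher and 3980 lower in GM-CSF cells, of which 2490 and 1607 by at least 2-fold. In the authors' deposited table of the same comparison 9336 genes were listed, 8993 of them were tested here, all with the same sign, and 8731 were also called here, with a Pearson r of 0.9875 between the log2 fold changes across these genes, which are not independent of one another.

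**Figure D2:**
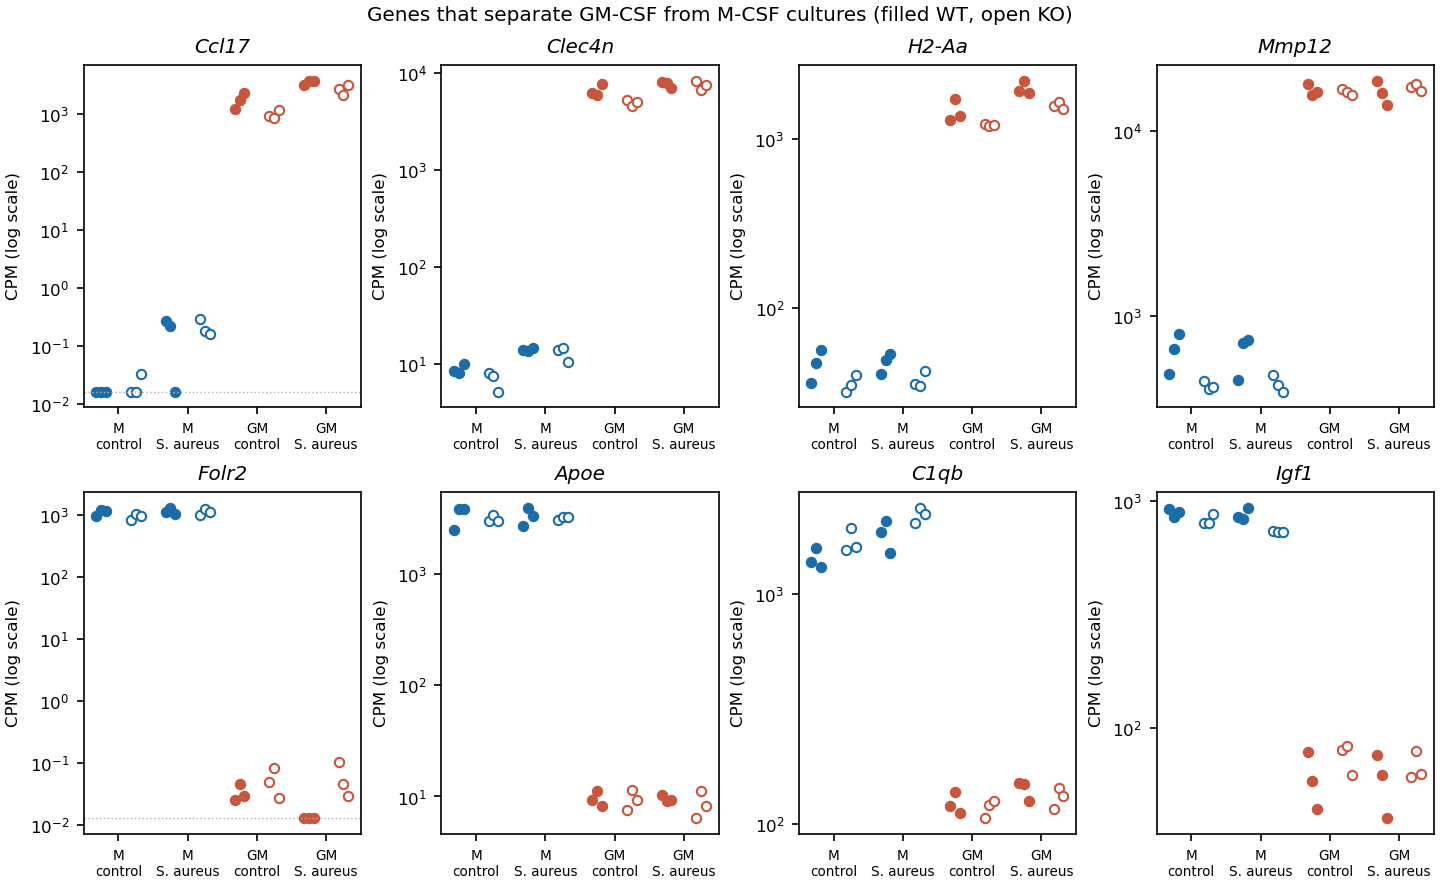
CPM on log axes of 8 genes in each of the 24 libraries by group, blue for M-CSF and red for GM-CSF, filled for WT and open for KO; libraries with 0 counts are drawn on the dotted line, at a fraction of the smallest value above 0. Ccl17, Clec4n, H2-Aa and Mmp12 are higher in every GM-CSF library, and Folr2, Apoe, C1qb and Igf1 are higher in every M-CSF library.

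After S. aureus many genes differed between the cytokines as at rest, and others changed sides. In GM-CSF WT cells Ccl17 averaged 3612 ± 326 CPM against 0.169 CPM in M-CSF cells (14.37 ± 0.38). The interleukin 1 decoy receptor Il1r2 was higher (11.47 ± 0.28), and Asgr2, Adam23 and Cbln1 had 0 counts in M-CSF cells and were at least 1260-fold, 1040-fold and 736-fold higher. Folr2 had 0 counts in GM-CSF S. aureus cells and was at least 31900-fold lower, and Cpe, also with 0 counts there, at least 517-fold lower. Hmga2 (-9.90), Col18a1 (-9.34), Cd5l (-9.07) and Pcp4l1 (-10.27) were lower too. MHC class II genes again differed, 13 of 14 higher, with H2-Eb1 at 6.26 (set adjusted p = 4.11e-24). Genes of alternative activation were higher in 11 and lower in 2 of 14 cases (set adjusted p = 8.32e-10), alveolar genes higher in 11 and lower in 4 of 17 (set adjusted p = 9.96e-05), and tissue-resident genes lower in 20 and higher in 4 of 26 (set adjusted p = 1.52e-11). Cytokines were higher in 15 of 21 cases, such as Il6 (5.61), Tnf (1.35) and Inhba (7.92), and lower in 4, among them Il10 (-6.34; set adjusted p = 1.74e-06). Chemokines were higher in 12 and lower in 7 of 21 (set adjusted p = 0.00667; adjusted p = 0.260 with an estimated correlation).

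Interferon response and NF-kB genes lay on the other side than at rest. Of 31 interferon response genes 24 were now higher in GM-CSF cells, such as Rsad2 (3.36) and Ifnb1 (6.83), and 2 lower (set adjusted p = 0.000216; adjusted p = 0.606 with an estimated correlation). Of 28 NF-kB genes 21 were lower, such as Dusp1 (-4.46) and Icam1 (-1.97), and 4 higher (set adjusted p = 1.35e-08). Antimicrobial genes were higher in 12 and lower in 4 of 22 (set adjusted p = 0.00667; adjusted p = 0.371 with an estimated correlation), cell cycle genes higher in 25 of 30, with Bub1b at 2.55 (set adjusted p = 0.0212; adjusted p = 0.806 with an estimated correlation), and genes of cholesterol synthesis and uptake lower in 18 of 24, with Hmgcs1 at -1.19 (set adjusted p = 0.0272; adjusted p = 0.544 with an estimated correlation). The counts adjusted over the list alone were the same for these lists, except 22 lower for the NF-kB genes. In all, 9718 genes differed, 4991 higher and 4727 lower in GM-CSF cells. Of the genes called at rest and after S. aureus, 3598 were higher in both and 2772 lower in both, where chance would give 1850 and 1340, and 904 changed sides.

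The response to S. aureus was read first in M-CSF WT cells. Cytokine genes rose from very low levels: Il1b went from 0.745 ± 0.829 to 3354 ± 164 CPM (12.13 ± 0.41), Il12b from 0.292 ± 0.404 to 1077 ± 113 CPM (11.84 ± 0.39), Tnf from 36.8 ± 0.408 to 3669 ± 78.4 CPM (6.64 ± 0.15) and Il1a to 338 ± 38.2 CPM (11.40 ± 0.23). Il6, with 1 count in the control libraries, rose to 60.2 ± 9.66 CPM, a ratio of 6480 with a 95% counting interval of 1160 to 256000. The cytokine signal inhibitor Socs3 (10.92 ± 0.31), the chemokine Cxcl3 (10.91 ± 0.30) and the nitric oxide synthase Nos2 (10.64 ± 0.36) rose as well, and Shisa3 rose from 2 counts to 112 ± 16.9 CPM. Among the genes of at least 10 CPM with the largest falls were the transcription factor Sox4 (-5.75 ± 0.31), the cannabinoid receptor Cnr2 (-5.46 ± 0.15), the ERK phosphatase Dusp6 (-4.62 ± 0.16), the lysophosphatidic acid receptor Lpar6 (-4.35), Zfp395 (-4.35), Snx30 (-4.20) and the homeobox gene Hhex (-3.85).

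All 28 NF-kB genes rose, among them the inhibitor Nfkbiz (7.05), the phosphatase Dusp2 (7.02) and the cyclooxygenase Ptgs2 (10.50; set adjusted p = 5.16e-112). Of 21 cytokines 20 rose and Il33 was not called (set adjusted p = 1.31e-34). Of 21 chemokines 20 rose, such as Cxcl1 (10.40), Cxcl2 (8.96) and Ccl5 (6.27), and Cxcl14 fell (-0.51; set adjusted p = 5.87e-20). Of 22 antimicrobial genes 16 rose, among them Irg1 (10.16), the mitochondrial superoxide dismutase Sod2 (4.46) and Saa3 (5.70; set adjusted p = 2.95e-15). Among 28 genes of pattern recognition 16 rose, such as Clec4e (6.83) and Tlr2, the receptor for bacterial lipoproteins (4.61), and 7 fell, such as Tlr13, the receptor for bacterial ribosomal RNA (-2.17; set adjusted p = 8.25e-07; adjusted p = 0.0575 with an estimated correlation). Interferon response genes rose in 17 of 31 cases, with Gbp5 at 6.67 and Ifnb1 at 5.30, and Ifit3 fell (-0.81; set adjusted p = 0.000616; adjusted p = 0.690 with an estimated correlation). Cell cycle genes fell in 22 of 30 cases, such as Kif11 (-1.97) and Ccne2 (-2.24), and Mki67 rose (1.95; set adjusted p = 0.000699; adjusted p = 0.690 with an estimated correlation). Other HIF-1 target genes rose in 13 and fell in 8 of 31 cases, with Adm at 5.77 and Ankrd37 at -1.22 (set adjusted p = 0.0108; adjusted p = 0.304 with an estimated correlation), and tissue-resident genes rose in 5 and fell in 13 of 26, with Mertk at -2.68 (set adjusted p = 0.0357; adjusted p = 0.681 with an estimated correlation). In all, 8463 genes responded, 4235 up and 4228 down, of which 1546 and 1723 by at least 2-fold. With DESeq2 size factors the balance turned, and 4009 rose and 4435 fell.

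In GM-CSF WT cells the same stimulus raised an interferon programme along with the cytokines. Ifnb1, which encodes interferon beta, rose from 0.0976 ± 0.0426 to 436 ± 26.6 CPM (12.11 ± 0.43; chromosome 4, 88522025 to 88522774). Il23a, a subunit of interleukin 23, rose from 1 count to 74.6 ± 10.9 CPM, a ratio of 8660 with a 95% counting interval of 1550 to 342000. Il6 (11.34 ± 0.26), Il12b (10.75 ± 0.34), the growth factor Ereg (9.39 ± 0.39), Ptgs2 (9.18 ± 0.31) and the interferon-induced chemokines Cxcl10 (7.92 ± 0.30) and Cxcl11 (8.46 ± 0.58) rose. B3gnt7 (-3.65 ± 0.19), Cnr2 (-3.51 ± 0.11), Fam78a (-3.39), Arhgef10l (-2.71), Cd300lb (-2.63) and Zfp36l2 (-2.59) fell.

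All 31 interferon response genes rose, such as Ifit2 (6.17) and Cmpk2 (6.11; set adjusted p = 6.29e-54). So did all 28 NF-kB genes, with Cd40 at 5.33 and Bcl3 at 0.54 (set adjusted p = 7.06e-49). Of 21 cytokines 20 rose, among them Il1b to 11200 CPM (6.64) and Tnfsf15 (6.63; set adjusted p = 1.99e-55). Of 21 chemokines 18 rose, such as Cxcl9 (6.84; set adjusted p = 1.39e-19), and of 28 genes of pattern recognition 17 rose and 4 fell, with Tlr3 at 2.69 and Tlr4 at -0.83 (set adjusted p = 3.89e-09). Antimicrobial genes rose in 17 of 22 cases (set adjusted p = 1.98e-09). Cell cycle genes fell in 19 and rose in 2 of 30 cases, with Bub1b at -1.30 and Mki67 at 1.55 (set adjusted p = 0.0129; adjusted p = 0.914 with an estimated correlation). Other HIF-1 target genes rose in 16 and fell in 7 of 31, with Egln3 going from 8.21 ± 1.53 to 142 ± 19.3 CPM (4.10; set adjusted p = 0.00727; adjusted p = 0.181 with an estimated correlation). For the lists of these 2 responses the counts adjusted over the list alone were the same, except 18 antimicrobial genes up and 3 cell cycle genes up and 20 down in GM-CSF cells and 24 cell cycle genes down in M-CSF cells. In all, 8237 genes responded, 3799 up and 4438 down, of which 1601 and 1256 by at least 2-fold. With DESeq2 size factors the balance turned, and 4162 rose and 4002 fell.

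The size of the response was then compared between the cytokines by the test of the difference, GM-CSF minus M-CSF. Interferon response genes had a higher response in GM-CSF cells in 28 of 31 cases (29 adjusted over the list alone), among them Ifnb1 (6.81 ± 1.77), Ifit3 (6.27 ± 0.33), Ifit2 (5.96 ± 0.37), Rsad2 (5.94 ± 0.29) and Cmpk2 (5.79 ± 0.27), and Gbp5 had a lower one (-1.71 ± 0.19; set adjusted p = 6.15e-39; adjusted p = 0.0629 with an estimated correlation). Il23a reached 74.6 CPM in GM-CSF and 1.89 CPM in M-CSF cells, and Il10 reached 5.70 CPM from 0 counts in GM-CSF and 461 CPM from 13.3 in M-CSF cells. NF-kB genes rose less in GM-CSF cells in 27 of 28 cases, with Socs3 at -7.40 ± 0.34, Tnfaip2 at -4.15 ± 0.18 and Dusp2 at -4.07 ± 0.22 (set adjusted p = 1.77e-64). The response was also lower for 14 of 22 antimicrobial genes, with Irg1 at -6.84 ± 0.35, Lcn2 at -6.08 and Slc7a11 at -5.67, while Hmox1, the haem oxygenase, had a higher one (1.25; set adjusted p = 7.82e-08; adjusted p = 0.112 with an estimated correlation). Chemokines had a lower response in 10 and a higher one in 3 of 21 cases (4 higher adjusted over the list alone, the other lists here unchanged), with Cxcl3 at -7.89 and Cxcl9 at 5.19 (set adjusted p = 0.000118; adjusted p = 0.153 with an estimated correlation), and cytokines a lower one in 9 and a higher one in 4 of 21, with Il1b at -5.49 and Osm at 1.16 (set adjusted p = 0.0261; adjusted p = 0.320 with an estimated correlation). Other large differences were in the survival gene Bcl2a1a (-7.54), which has near-identical copies, and endothelin 1 (Edn1, -7.36), both with the smaller response in GM-CSF cells. A smaller rise went with a higher resting level for Socs3, which stood at 78.9 CPM in GM-CSF and 0.951 CPM in M-CSF control cells, and for Irg1, at 398 and 2.15 CPM. In all, 5225 genes differed in response, 2134 toward a higher and 3091 toward a lower value in GM-CSF cells, and with DESeq2 size factors 2525 and 2558. Of the genes called in both responses, 2391 rose in both and 2798 fell in both, where chance would give 1150 and 1340, and 737 with a called difference moved in opposite directions. Across genes, which are not independent replicates, the Pearson r of the responses was 0.583.

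**Figure D3:**
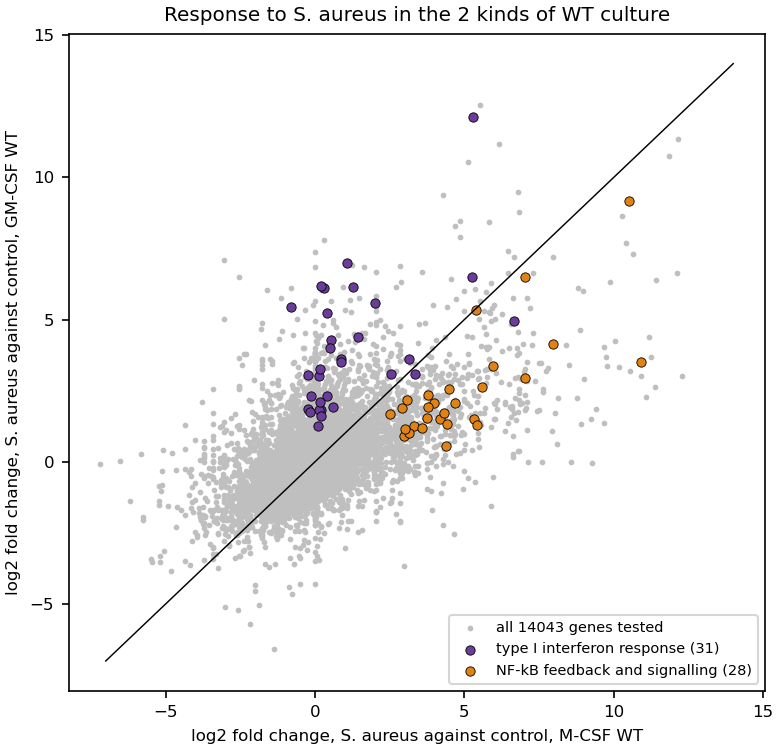
Log2 fold change of S. aureus against control in WT cells for 14043 genes, M-CSF on the x axis and GM-CSF on the y axis, each point 1 gene from 3 libraries per group, with 31 interferon response genes in purple, 28 NF-kB genes in orange and the line of equal responses. Interferon response genes lie mostly above the line and NF-kB genes below it.

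KO cells answered S. aureus with changes close to those of WT cells. In M-CSF KO cells Il1b rose to 2331 ± 90.5 CPM (12.22 ± 0.41), Tnf to 3024 ± 242 CPM (6.44 ± 0.15) and Il12b to 1219 ± 47.7 CPM (13.33 ± 0.43), and all 28 NF-kB genes rose (set adjusted p = 4.07e-111). In GM-CSF KO cells Ifnb1 rose by 12.80 ± 0.47 and Il6 by 10.92 ± 0.25, and all 31 interferon response genes rose (set adjusted p = 1.41e-54). In M-CSF KO cells 8370 genes responded, 4113 up and 4257 down, and in GM-CSF KO cells 8924, 4024 up and 4900 down. With DESeq2 size factors the balance turned in GM-CSF KO cells, with 4429 up and 4349 down. Of the genes called in WT and KO M-CSF cells 3404 rose in both, 3549 fell in both and 2 moved in opposite directions, and in GM-CSF cells 3168, 3834 and 2. Across genes the Pearson r of WT and KO responses was 0.909 in M-CSF and 0.905 in GM-CSF cells.

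The comparison of KO with WT cells asked which genes differ between cells with and without the Hif1a deletion. No group carried Cre with an unflanked Hif1a. Effects of Cre, of its insertion into Lyz2 and of the deletion therefore cannot be told apart. As the mean of the 4 conditions, listed HIF-1 targets were lower in KO cells: the prolyl hydroxylase Egln3, which marks HIF-1alpha for degradation (-1.63 ± 0.17; chromosome 12, 54178981 to 54203860), Narf (-1.32 ± 0.07; chromosome 11, 121237253 to 121255856), the mitophagy receptor Bnip3 (-0.85 ± 0.06; chromosome 7, 138890836 to 138909519) and the growth factor Vegfa (-0.66 ± 0.07). Ankrd37 (-2.61 ± 0.17) and the adenylate kinase Ak4 (-2.01 ± 0.12), both under 10 CPM in every group, fell furthest among the listed targets. In the glycolytic pathway the phosphofructokinase Pfkl (-0.88 ± 0.06; chromosome 10, 77986947 to 78010083) and the lactate exporter Slc16a3 (-0.80 ± 0.06; chromosome 11, 120948480 to 120960868) were lower, as were Tpi1 (-0.38), Eno1 (-0.35), Hk2 (-0.33) and the glucose transporter Slc2a1 (-0.40). Arg1 (-0.82 ± 0.16), the acute-phase gene Saa3 (-0.66 ± 0.15) and the cytokine Mif (-0.64 ± 0.04) were lower too. Genes higher in KO cells included Lyz1, the cytokinesis gene Anln (0.74 ± 0.11), Arhgef37 (0.85 ± 0.20), Prc1 (0.66 ± 0.10) and the topoisomerase Top2a (0.65 ± 0.11).

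Of 31 other HIF-1 target genes 18 were lower in KO and 1, the lipid droplet gene Plin2 (0.20), was higher (20 lower and 1 higher adjusted over the list alone; set adjusted p = 5.36e-35). Glycolysis genes were lower in 10 of 26 cases and Slc2a6 was higher (0.19), or 12 lower and 2 higher adjusted over the list alone (set adjusted p = 7.43e-12; adjusted p = 0.0877 with an estimated correlation). Cell cycle genes were higher in 24 of 30 cases, such as the kinesin Kif20a (0.54) and the ribonucleotide reductase gene Rrm2 (0.53), or 27 higher and 1 lower adjusted over the list alone (set adjusted p = 9.27e-24; adjusted p = 0.0850 with an estimated correlation). Cholesterol genes were higher in 13 of 24 cases (15 adjusted over the list alone), with Dhcr7 at 0.34 and Cyp51 at 0.30 (set adjusted p = 5.27e-09; adjusted p = 0.0829 with an estimated correlation). Genes of ER stress and the amino acid response were higher in 8 of 21 cases (8 adjusted over the list alone), with the serine synthesis enzyme Phgdh at 0.62 and the chaperone Hspa5 at 0.30 (set adjusted p = 3.45e-06; adjusted p = 0.0829 with an estimated correlation). Fatty acid oxidation genes were higher in 5 of 18 cases (7 adjusted over the list alone), with Hadhb at 0.29 (set adjusted p = 0.00284; adjusted p = 0.418 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation were lower in 16 and higher in 6 of 43 cases (18 and 7 adjusted over the list alone), with Cox7b at -0.33 and Ndufs1 at 0.17 (set adjusted p = 1.76e-05; adjusted p = 0.581 with an estimated correlation). Across genes the mean log2 fold change rose with exon length (Spearman rho 0.159), and 66 of 85 ribosomal protein genes were lower. MHC class II genes were lower in 4 of 14 cases (5 adjusted over the list alone), with H2-Aa at -0.34 (set adjusted p = 0.01; adjusted p = 0.301 with an estimated correlation). In all, 1850 genes differed, 1040 higher and 810 lower in KO cells, of which 2 and 19 by at least 2-fold. Of 34 genes named for this mean with a call, 31 had the KO mean on the same side in all 4 conditions, and Saa3, Slc2a1 and Slc2a6 in 3. Among the 24 fits without 1 library, Plin2 lost its call in 18 and Slc2a6 in 15, and the other named genes kept theirs in all 24. The labels do not say whether replicates came from separate mice or separate cultures. The fit takes all 24 libraries as independent, although control and S. aureus libraries of the same number correlated in GM-CSF KO cells. These p-values therefore measure the spread between these libraries, not between independent replicates.

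**Figure D4:**
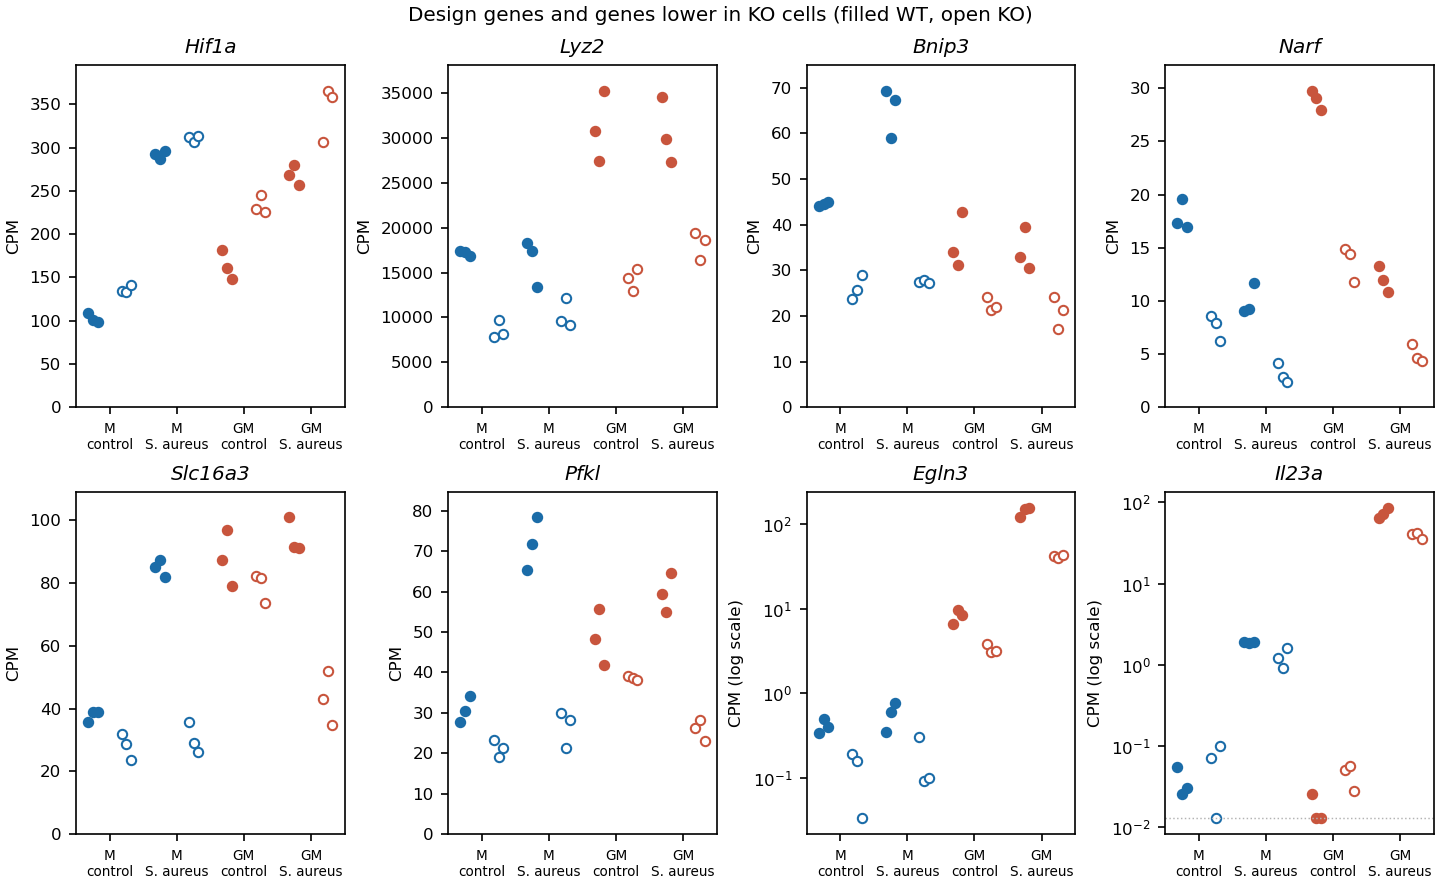
CPM of 8 genes in each of the 24 libraries by condition, on linear axes from 0 for Hif1a, Lyz2, Bnip3, Narf, Slc16a3 and Pfkl and on log axes for Egln3 and Il23a; blue for M-CSF and red for GM-CSF, filled for WT and open for KO. Lyz2, Bnip3 and Narf are lower in each KO group than in its WT group, and Hif1a is not.

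In M-CSF control cells KO libraries held less Saa3, at 5.63 ± 0.145 against 20.1 ± 11.4 CPM (-1.83 ± 0.34; chromosome 7, 46711998 to 46715700), the fatty acid binding protein Fabp7 (-1.12 ± 0.25), the beta-glucan receptor Clec7a (-0.79 ± 0.16), Narf (-1.23 ± 0.14), Bnip3 (-0.77 ± 0.11) and the long noncoding RNA Neat1 (-0.69 ± 0.13). Mitotic genes such as Anln (1.11 ± 0.22), Top2a (1.10 ± 0.22), Ect2 (1.02), Kif20a (1.00) and Ccna2 (0.94) were higher, as was the ER stress gene Herpud1 (0.93 ± 0.10). Cell cycle genes were higher in 17 of 30 cases and Pcna was lower (-0.30), or 25 higher and 1 lower adjusted over the list alone (set adjusted p = 2.78e-16; adjusted p = 0.287 with an estimated correlation). Other HIF-1 targets were lower in 8 of 31 cases, with Ndrg1 higher (0.66), or 10 lower and 1 higher adjusted over the list alone (set adjusted p = 3.04e-05; adjusted p = 0.0880 with an estimated correlation). Oxidative phosphorylation genes were lower in 14 and higher in 2 of 43 cases (18 and 6 adjusted over the list alone), with Cox7b at -0.53 and Ndufb9 at -0.52 against Sdha at 0.31 (set adjusted p = 3.38e-06; adjusted p = 0.794 with an estimated correlation). Across 13978 genes, which are not independent, the log2 fold change rose with exon length (Spearman rho 0.259), and 47 of 85 ribosomal protein genes were lower. ER stress genes were higher in 7 of 21 cases (9 adjusted over the list alone; set adjusted p = 3.05e-06; adjusted p = 0.0880 with an estimated correlation), and cholesterol genes in 4 of 24 (13 adjusted over the list alone; set adjusted p = 3.59e-05; adjusted p = 0.303 with an estimated correlation). The 1081 genes called, 607 higher and 474 lower, came to 29 without KO replicate 1, 217 without KO replicate 2, 324 without WT replicate 2 and 11 (4 higher and 7 lower) without WT replicate 3. The balance turned in a fit of the compared groups alone, with 1016 higher and 1219 lower, and without the low-count filter, with 701 and 740. Of the 19 genes named with a call here, 4 (Lyz2, Narf, Bnip3 and Herpud1) were also called without KO replicate 1 and without WT replicate 3, 13 without KO replicate 2, 14 without WT replicate 2, and 17 without KO replicate 3 or WT replicate 1. Pcna and Sdha lost their calls in each of the 6 fits without 1 library. The oxidative phosphorylation genes called lower came to 0 without KO replicate 1 or WT replicate 3, 1 without KO replicate 2, 3 without WT replicate 2 and 8 without KO replicate 3, and the cell cycle genes called higher to 1 without KO replicate 1 or WT replicate 3 and 8 without WT replicate 2.

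After S. aureus, M-CSF KO cells held less of several glycolytic and hypoxia-response transcripts than WT cells. Slc16a3 reached 30.4 ± 4.94 CPM in KO and 84.9 ± 2.70 CPM in WT (-1.48 ± 0.12), Pfkl 26.5 ± 4.66 and 71.8 ± 6.55 CPM (-1.44 ± 0.12) and the glucose transporter Slc2a1 73.8 ± 6.16 and 143 ± 13.9 CPM (-0.95 ± 0.12). The zinc finger gene Zfp292 (-1.28 ± 0.13), Bnip3 (-1.24 ± 0.12), Vegfa (-1.14 ± 0.14), the histone demethylase Kdm3a (-0.92 ± 0.09), Neat1 (-0.98), Slc7a11 (-0.95) and the neutrophil growth factor Csf3 (-0.94) were lower. The fibrinogen-like Fgl2 (1.00 ± 0.16), Phgdh (0.91 ± 0.19) and the interferon-induced Ifit2 (0.98 ± 0.24), Ifit3 (0.80) and Cxcl10 (0.82) were higher. Other HIF-1 targets were lower in 14 of 31 cases (20 lower and 3 higher adjusted over the list alone; set adjusted p = 7.54e-25) and glycolysis genes in 9 of 26 (11 lower and 1 higher adjusted over the list alone; set adjusted p = 4.08e-14; adjusted p = 0.0646 with an estimated correlation). Interferon response genes were higher in 5 of 31 cases (12 higher and 1 lower adjusted over the list alone; set adjusted p = 9.77e-10; adjusted p = 0.393 with an estimated correlation), cell cycle genes in 7 of 30 (17 adjusted over the list alone; set adjusted p = 2.28e-13; adjusted p = 0.235 with an estimated correlation), fatty acid oxidation genes in 6 of 18 (10 adjusted over the list alone; set adjusted p = 6.79e-09; adjusted p = 0.0646 with an estimated correlation) and ER stress genes in 5 of 21 (7 adjusted over the list alone; set adjusted p = 5.79e-07; adjusted p = 0.0594 with an estimated correlation). Cytokines were lower in 3 of 21 cases, Il1a (-0.68), Lif (-1.11) and Csf3 (5 adjusted over the list alone; set adjusted p = 0.000189; adjusted p = 0.0646 with an estimated correlation). The 482 genes called, 263 higher and 219 lower, came to 124 (53 and 71) without KO replicate 1, 80 (32 and 48) without KO replicate 2 and 59 (16 and 43) without WT replicate 3, and to 301 higher and 314 lower in a fit of the compared groups alone, so the balance turned in each of these. Of the 18 genes named with a call here, 12 were also called without KO replicate 1, 13 without KO replicate 2 or WT replicate 3 and 17 without WT replicate 2. Cxcl10 lost its call in each of these fits, and Ifit2, Ifit3 and Slc7a11 in the first 3 of them.

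In GM-CSF control cells KO libraries held less Arg1, at 4.77 ± 1.31 against 10.8 ± 2.83 CPM (-1.18 ± 0.23), Narf (-1.08 ± 0.14), Ccl17, at 989 ± 168 against 1774 ± 544 CPM (-0.84 ± 0.20; chromosome 8, 94810453 to 94812036), the costimulatory receptor Cd40 (-0.70 ± 0.11), Mif (-0.68 ± 0.08) and Bnip3 (-0.67 ± 0.11). The mannose receptor Mrc1 (0.93 ± 0.20), the sorting receptor Sort1 (0.70), the monoamine oxidase Maoa (0.65) and the neutrophil granule gene Ngp (1.14 ± 0.29) were higher. The granule genes Ltf (1.18) and Mpo (3.19), looked up after Ngp was seen, were higher beside it, at 17.9, 9.20 and 1.70 CPM in KO. They were the 3 called of 13 neutrophil markers (set adjusted p = 0.0208; adjusted p = 0.439 with an estimated correlation). Other HIF-1 targets were lower in 7 of 31 cases, such as Higd1a (-0.52) and Fam162a (-0.60), or 10 lower and 1 higher adjusted over the list alone (set adjusted p = 1.34e-08). Oxidative phosphorylation genes were lower in 12 of 43 cases (23 lower and 1 higher adjusted over the list alone), with Cox7a2 at -0.55 (set adjusted p = 1.27e-10; adjusted p = 0.439 with an estimated correlation). Here too the log2 fold change rose with exon length across genes (Spearman rho 0.283), and 55 of 85 ribosomal protein genes were lower. Cholesterol genes were higher in 7 of 24 cases (12 adjusted over the list alone), with Dhcr7 at 0.58 (set adjusted p = 2.19e-07; adjusted p = 0.232 with an estimated correlation), and cell cycle genes in 6 of 30 (11 adjusted over the list alone), with Mcm4 at 0.58 (set adjusted p = 4.08e-08; adjusted p = 0.439 with an estimated correlation). The 448 genes called, 127 higher and 321 lower, came to 18 without KO replicate 1 and 19 (11 higher and 8 lower) without KO replicate 2. They came to 728 without KO replicate 3, 1070 without WT replicate 1, 251 without WT replicate 2 and 11 without WT replicate 3. In a fit of the compared groups alone they came to 6, with 0 higher and 6 lower. No gene given as higher in KO in this condition kept its call in that fit. Of the genes called in M-CSF and GM-CSF control cells, 51 were higher in KO in both and 205 lower in both, where chance would give 5.49 and 10.8. Of the 19 genes named with a call here, 11 were also called without KO replicate 1, 10 without KO replicate 2, 18 without KO replicate 3, 16 without WT replicate 2 and 7 without WT replicate 3, with Ngp lost each time and Ccl17 and Mrc1 in all but the fit without KO replicate 3. The oxidative phosphorylation genes called lower came to 0 without KO replicate 1, KO replicate 2 or WT replicate 3, 7 without WT replicate 2 and 19 without WT replicate 1.

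After S. aureus, GM-CSF KO cells were lower in Egln3, at 41.3 ± 1.82 CPM against 142 ± 19.3 in WT (-1.78 ± 0.12), in Pfkl (-1.21 ± 0.12), Slc16a3 (-1.14 ± 0.12), Narf (-1.28 ± 0.16), Egln1 (-0.82 ± 0.10), Bnip3 (-0.71) and Mif (-0.75). The cytokine subunit Il23a was lower, at 39.1 ± 3.77 against 74.6 ± 10.9 CPM (-0.93 ± 0.12), as was the transglutaminase F13a1 (-0.93 ± 0.14). Pparg was higher (0.39 ± 0.08). Other HIF-1 targets were lower in 11 of 31 cases (20 lower and 1 higher adjusted over the list alone; set adjusted p = 2.39e-43), glycolysis genes in 3 of 26 (12 adjusted over the list alone; set adjusted p = 1.33e-21) and cytokines in 2 of 21, Il23a and Csf2 (-1.42), or 7 lower and 1 higher adjusted over the list alone (set adjusted p = 2.29e-07). As sets, NF-kB genes (11 of 28 lower adjusted over the list alone, 0 over all genes; set adjusted p = 5.79e-09), MHC class II genes (8 of 14 and 0; set adjusted p = 1.11e-06) and genes of alternative activation (4 of 14 and 0; set adjusted p = 0.00939) were lower. Across genes the log2 fold change fell with GC content here (Spearman rho -0.228). No set of this condition was compared with random lists matched on GC content, so a part of this trend in the sets stays open. In all, 25 genes differed, 2 higher, Pparg and the predicted gene Gm10116, which was named only after its value was seen, and 23 lower, and the count came to 43 without KO replicate 2 and 38 without WT replicate 1. Pparg lost its call without KO replicate 2, KO replicate 3, WT replicate 2 or WT replicate 3, and Lyz2 without WT replicate 1.

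The dependence of the response on genotype was tested as KO minus WT. In M-CSF cells 4 genes differed, all toward a lower value in KO: Kdm3a (-0.86 ± 0.13, adjusted p = 0.00466), Zfp292 (-1.13 ± 0.17, adjusted p = 0.00485), Slc16a3 (-1.05 ± 0.17, adjusted p = 0.0114) and Pfkl (-0.90 ± 0.17, adjusted p = 0.0438). Pfkl lost its call with the replicate number as a block (adjusted p = 0.0800), with the block within genotype (adjusted p = 0.0530) and in a fit of the compared groups alone (-0.86), and the other 3 kept theirs. The direction of the genes called depended on the fit: 13 were higher and 7 lower in the compared groups alone, 41 and 34 without the low-count filter, and 6 and 20 by DESeq2. Glycolysis genes went the same way as a set (4 of 26 lower adjusted over the list alone and 2 over all genes; set adjusted p = 4.15e-08; adjusted p = 0.556 with an estimated correlation), as did other HIF-1 targets (10 lower and 1 higher of 31 adjusted over the list alone, 1 lower over all genes; set adjusted p = 3.58e-05; adjusted p = 0.190 with an estimated correlation). In GM-CSF cells edgeR called 0 genes, with 2016 at an unadjusted p under 0.05, and DESeq2 called 3. With the replicate number as a block edgeR called 1, Slc16a3. The smallest p-values there were those of Slc16a3 (-0.99, adjusted p = 0.0630), Pfkl (-0.88, adjusted p = 0.109), the ribosomal pseudogene Rps27a-ps2 (1.40, adjusted p = 0.277), Egln1 (-0.63, adjusted p = 0.277) and the glycogen synthase Gys1 (-0.63, adjusted p = 0.301). The glycolysis list was lower as a set (5 of 26 adjusted over the list alone; set adjusted p = 4.59e-08; adjusted p = 0.510 with an estimated correlation). The count in M-CSF cells came to 2 without KO control replicate 1, KO S. aureus replicate 2, KO S. aureus replicate 3 or WT S. aureus replicate 2, where Pfkl and Slc16a3 lost their calls. Both also lost them without WT control replicate 1, and Pfkl without KO control replicate 3, WT control replicate 2 or WT S. aureus replicate 3. In GM-CSF cells the count came to 2 without WT control replicate 2, 1 without KO S. aureus replicate 1 and 25 without KO S. aureus replicate 2.

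Whether the KO effect differed between the cytokines was tested as GM-CSF minus M-CSF. In control cells 1 gene differed, Herpud1 (-0.98 ± 0.14, adjusted p = 0.00215), which was higher in KO in M-CSF cells and -0.04 in GM-CSF cells (adjusted p = 0.827). In a fit of the compared groups alone Herpud1 lost its call (-0.94, adjusted p = 0.150), and without the low-count filter 24 genes differed toward a higher and 22 toward a lower value. After S. aureus 51 genes differed, 21 toward a higher and 30 toward a lower KO effect in GM-CSF cells. They included Neat1 (1.13 ± 0.19), Csf3 (1.13 ± 0.20), Zfp292 (0.97 ± 0.17) and the iron importer of mitochondria Slc25a37 (0.93 ± 0.16) on the higher side, and the cell adhesion gene Pvrl2 (-0.86 ± 0.14) on the lower. Interferon response genes were lower as a set by this measure in control cells (set adjusted p = 7.96e-09; adjusted p = 0.614 with an estimated correlation) and after S. aureus (set adjusted p = 2.05e-10; adjusted p = 0.575 with an estimated correlation), with 0 of 31 called over all genes and 15 adjusted over the list alone. The 51 came to 18 without M-CSF KO replicate 1, 0 without M-CSF KO replicate 2, 79 without M-CSF WT replicate 1, 0 without M-CSF WT replicate 3, 0 without GM-CSF KO replicate 1, 174 without GM-CSF KO replicate 2 and 18 (11 higher and 7 lower) without GM-CSF WT replicate 3, and the 1 of control cells to 2 without M-CSF KO replicate 3. With the replicate number as a block the 51 came to 102, and to 107 with the block within genotype.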

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

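Of the tests in this part, the 3 that concern the Hif1a counts, and the use of matched random lists against the scaling, were chosen only after the result was seen. So were the relation with exon length and the count of ribosomal protein genes.

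The response to S. aureus differed between M-CSF and GM-CSF WT cells in 5225 genes by the test of the difference, and 737 of these moved in opposite directions, each called in both. In M-CSF cells the response differed between KO and WT in 4 genes, Kdm3a (-0.86), Zfp292 (-1.13), Slc16a3 (-1.05) and Pfkl (-0.90). The KO effect differed between the cytokines in 1 gene in control cells, Herpud1 (-0.98), and in 51 genes after S. aureus. The 5 of these 51 with the smallest p were Pvrl2 (-0.86), Slc25a37 (0.93), Neat1 (1.13), Fosl2 (0.70) and 5031414D18Rik (-0.96), a predicted gene outside the naming rule that was named after its value was seen. Single libraries were not tested against their groups, which hold 3 each. On the fourth principal component (1.09% of the variance) GM-CSF WT control replicate 3 lay at -26.6 against -0.92 and -0.43 for the other 2 of its group, and GM-CSF KO S. aureus replicate 2 at 18.6 against -9.70 and -12.8. By chi-square per degree of freedom of the counts the first differed from its partners by 36.4 and 47.3 (25.7 between the partners), and the second by up to 58.2 (22.1). Without the first the KO effect in GM-CSF control cells had 11 genes in place of 448. That count was also low without KO control replicate 1 (18) and without KO control replicate 2 (19), so it does not depend on the first alone. Other libraries stood apart as well. By chi-square M-CSF WT S. aureus replicate 3 differed from its partners by 27.5 and 25.7 (8.93 between the partners). M-CSF KO S. aureus replicate 2 differed from its partners by 14.8 and 23.3 (7.69 between the partners). On the fourth component GM-CSF KO control replicate 2 lay at 17.4 against 5.18 and 0.92.

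Hif1a counts were higher, not lower, in KO libraries. Exchanged labels are argued against by Lyz2, which was lower in every KO than in every WT library in 4 of 4 conditions. The list of other HIF-1 targets was lower in KO, with an adjusted p of 6.38e-06 by camera with an estimated correlation. No group carried Cre with an unflanked Hif1a, so the list cannot tell the deletion from an effect of Cre. Whether the KO cells carry the deletion is therefore not settled by these counts. Reads from exons left in a deleted transcript stay open and cannot be told apart from a true rise of the transcript, because counts per gene (mean difference 0.34) do not show the exon. A change of Hif1a transcription in KO cells was not tested.

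Nuclear-encoded oxidative phosphorylation genes were lower in unstimulated KO cells of both cytokines, while the set call was lost with an estimated correlation (adjusted p = 0.794 in M-CSF and 0.439 in GM-CSF cells). Exon length (all annotated exons of a gene joined), GC content and expression level do not account for all of it. Among 10000 random lists matched on these, the list's median lay at percentile 1.09 in M-CSF and 0.34 in GM-CSF cells. Random lists are, however, less correlated among their members than a pathway is. The length of the mature transcript was not matched and stays open. A scaling factor moves every gene alike, so the same percentiles argue against the scaling as the whole cause. DESeq2 size factors do not test it: 14 of 14 and 12 of 12 called members stayed lower, but these factors moved the median of all genes by only -0.010 and -0.018, further down. The median nearest 0 without 1 library was -0.136 in M-CSF (without KO replicate 1) and -0.148 in GM-CSF cells (without WT replicate 3), so the direction does not rest on 1 library. The members called came to 0 without KO replicate 1 or WT replicate 3 in M-CSF cells and without KO replicate 1, KO replicate 2 or WT replicate 3 in GM-CSF cells. In the same comparisons the log2 fold change rose with exon length across genes (Spearman rho 0.259 in M-CSF and 0.283 in GM-CSF cells). Of 85 ribosomal protein genes 47 and 55 were lower. The genotype stays open as an untested biological explanation, as does RNA quality, for which the files give no measure.

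Cell cycle genes were higher in M-CSF control KO cells, with the set call lost at an estimated correlation (adjusted p = 0.287). The list's median lay at percentile 100 of the matched random lists, whose members are less correlated than those of a pathway. This argues against exon length, GC content, expression level or scaling as the whole cause. Without KO replicate 1 the median was still 0.55 and without WT replicate 3 it was 0.607, each with 1 member called. The direction thus does not rest on 1 library, while the number of members called does depend on single libraries. Proliferating progenitors left in the KO cultures cannot be told apart from cycling macrophages: the median of 8 monocyte and progenitor markers was -0.089, and only Ccr2 of them reached 10 CPM in these cells. The cells had been sorted for CD11b and F4/80. An effect of the genotype on proliferation stays open as untested.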

How the results depend on the processing

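No test here was chosen only after the result was seen. The counts for the cytokine comparisons, the responses to S. aureus and the mean KO effect stayed within 1.5-fold under every alternative that could be fitted, and no gene or list reversed its direction past the threshold.

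Without the low-count filter the counts became 959 (KO, M-CSF S. aureus), 1011 (KO, GM-CSF control), 160 (KO, GM-CSF S. aureus), 75 and 31 (response difference KO minus WT in M-CSF and GM-CSF cells), and 46 and 517 (KO effect difference in control and S. aureus). With the DESeq2 Wald test they became 1676 (KO, M-CSF control), 990, 931, 75, 26, 3, 2 and 305 in the same order. In a fit of the compared groups alone they became 2235 (KO, M-CSF control), 6 (KO, GM-CSF control), 15 (KO, GM-CSF S. aureus), 20 (response difference in M-CSF cells), and 0 and 18 (KO effect difference in control and S. aureus). With the replicate block the response difference in GM-CSF cells had 1 gene and the KO effect difference after S. aureus 102, and with the block within genotype 1 and 107. Neither block moved another count by over 1.5-fold, and for the S. aureus response of GM-CSF KO cells, whose libraries the numbers pair, the count was 8973 with the block and no list or gene open to naming changed its call. Each library also correlated best with its own number in both M-CSF responses. Of 156 list calls, 50 held with an estimated correlation. The cause of these changes was not tested. In the fit of the compared groups alone the KO count rose from 1081 to 2235 in M-CSF control and fell from 448 to 6 in GM-CSF control. The smaller number of libraries alone does not account for changes in opposite directions. The main fit takes 1 spread per gene for all 8 groups. Chi-square per degree of freedom between replicates was 10.1 to 20.9 in the M-CSF control groups and 14.6 to 47.3 in the GM-CSF control groups. The shared spread may thus be too wide for M-CSF and too narrow for GM-CSF control cells, which was not tested. In the latter case the p-values of the main fit would be too small.

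Leaving out each library in turn gave 8555 to 8918 genes (cytokines, control), 9201 to 9362 (cytokines, S. aureus), 7731 to 7958 (S. aureus, M-CSF WT), 7577 to 8073 (GM-CSF WT), 7673 to 7962 (M-CSF KO), 8140 to 8852 (GM-CSF KO), 4747 to 5326 (response difference between the cytokines), 1364 to 2099 (mean KO effect), 11 to 858 (KO, M-CSF control), 59 to 506 (M-CSF S. aureus), 11 to 1070 (GM-CSF control), 17 to 43 (GM-CSF S. aureus), 2 to 6 and 0 to 25 (response difference KO minus WT in M-CSF and GM-CSF cells), and 1 to 2 and 0 to 174 (KO effect difference in control and S. aureus). The libraries behind the wide ranges are named with each comparison. Under DESeq2 size factors 2024 results of single genes open to naming kept their direction and their side of the threshold, 38 fell short of it and 2 came to pass it. In fits without 1 library 15228 such results kept both, 1317 fell short and 27 came to pass. In the compared groups alone these were 1925, 129 and 10, without the filter 1976, 52 and 36, with the DESeq2 Wald test 2021, 27 and 16, with the replicate block 2043, 11 and 10 and with the block within genotype 1617, 9 and 11. The balance of higher and lower genes turned with DESeq2 size factors and the DESeq2 Wald test in the responses of M-CSF WT, GM-CSF WT and GM-CSF KO cells to S. aureus. In M-CSF WT cells, with 4235 up and 4228 down, it also turned without the filter (3993 and 4368). The same held there with the replicate block (4268 and 4270) and with the block within genotype (4249 and 4267). The scaling moved the median of all genes by at most 0.083 (log2). Genes at 0 counts in a group have only a bound for their fold.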

Other observations

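Of the tests in this part, the relation of fold change with exon length and the count of ribosomal protein genes were chosen only after the result was seen. So were the relation with GC content, the splits that keep numbers together or exchange as many libraries in both conditions, the sorting of the splits by the share of a main effect that they carry or by the pairs that they part, and the use of adjusted p and of fits without 1 library against chance.

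Growth and repair factors parted by cytokine in unstimulated WT cells. The matrix glycoprotein Thbs1 (492 against 3.48 CPM), the membrane protease Mmp14 (7.18) and the EGF family member Hbegf (4.26) were higher in GM-CSF cells, and Igf1 (-3.89), the platelet-derived factor Pdgfb (-2.74) and the urokinase Plau (-1.57) were higher in M-CSF cells, so that 10 of 19 were higher and 7 lower (set adjusted p = 0.198). S. aureus raised Mmp14 by 7.93 in M-CSF and by 1.10 in GM-CSF cells, with a called difference (-6.84). Glycolysis genes went both ways: the glucose transporter Slc2a1 was higher (2.34) and Slc2a3 lower (-3.33) in GM-CSF cells, with 13 of 26 higher and 7 lower (set adjusted p = 0.495). The regulatory enzyme Pfkfb3 rose by 4.02 in M-CSF and 1.12 in GM-CSF cells after S. aureus (difference -2.90), while 9 and 9 glycolysis genes rose and 6 and 4 fell (set adjusted p = 0.231 and 0.655). In the TCA cycle the pyruvate carrier gene Mpc1 (1.47) and the carboxylase Pcx (2.56) were among 14 of 20 members higher in GM-CSF cells, against 2 lower (set adjusted p = 0.266).

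Of the mitochondrially encoded mRNAs 3 of 10 were higher in GM-CSF cells (set adjusted p = 0.668), of the pentose phosphate genes 4 of 7 (set adjusted p = 0.653), and of the immediate early and heat shock genes 7 of 17, with 5 lower (set adjusted p = 0.713). Among the immediate early genes Egr2 was higher (4.09) and Fos lower (-3.09). After S. aureus 10 of 17 rose and 4 fell in M-CSF cells (set adjusted p = 0.00940; adjusted p = 0.362 with an estimated correlation). The genes counted adjusted over the list alone were the same for these lists and comparisons. Among the marker lists of other cells not given in the report, Cd79b, a B cell marker, averaged 3.83 CPM in M-CSF and 0.323 CPM in GM-CSF control cells, and the mast cell markers Kit and Gata2 6.01 and 5.50 CPM in GM-CSF cells. The haemoglobin gene Hbb-bt averaged 0.329 CPM and the stromal gene Col1a1 0.462 CPM in GM-CSF control cells. The eotaxin receptor Ccr3, used as an eosinophil marker, averaged 40.7 CPM in M-CSF and 0.0824 CPM in GM-CSF control cells (-8.83).

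In unstimulated KO cells of both cytokines short genes tended to lower and long genes to higher values. Across 13978 genes, which are not independent, the Spearman rho of log2 fold change with exon length was 0.259 in M-CSF control, 0.283 in GM-CSF control, -0.069 in M-CSF S. aureus and -0.079 in GM-CSF S. aureus. With GC content it was 0.045, 0.007, 0.063 and -0.228 in the same order, so that genes rich in GC tended to lower values in GM-CSF KO cells after S. aureus. Of 85 ribosomal protein genes 47, 55, 0 and 0 were lower by edgeR in these conditions and 66 as the mean, with median log2 fold changes of -0.39, -0.45, -0.06, -0.13 and -0.26. Near-identical copies of these genes make their counts uncertain.

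The libraries were also split in other ways. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real counts were 9190 and 9718 for the cytokines, 8463, 8237, 8370 and 8924 for S. aureus and 1081, 482, 448 and 25 for KO, and the highest of the other splits was 1 (S. aureus in GM-CSF KO cells, and KO in M-CSF S. aureus cells) and otherwise 0. In GM-CSF KO cells, where the numbers pair the libraries, the 3 other splits that part 3 pairs called 0 genes each by edgeR, and the 6 that part 1 pair at most 1. For the mean KO effect 1 of 50 splits, the real one, reached 1850 genes, and the highest other gave 1. These splits take all libraries as independent, which the pairing in GM-CSF KO cells goes against. With the control and S. aureus libraries of the same cytokine, genotype and number kept together, again 1 of 50 reached 1850, and the highest other gave 557. This speaks against chance if libraries of different number are independent, which the labels do not say. If numbers were shared between the cytokines too, which the labels do not say either, the 10 splits left are too few for a share under 0.05. Chance is therefore not excluded. For the differences between effects the splits do not measure chance, since a split that exchanges more libraries in 1 condition than in the other turns part of a main effect into a difference. This is a structure of the samples. As many genes as the real 5225 came from 9 of 50 splits for the response difference between the cytokines (highest other 10444), and each of the other 8 carried at least 0.67 of the cytokine effect. The smallest adjusted p of this difference by edgeR was 6.14e-20, which speaks against chance as far as the libraries are independent. The fits without 1 library called at least 4747 genes, so the count does not rest on 1 library. Neither value excludes chance. For the response difference between KO and WT, 7 of 50 splits reached the 4 genes of M-CSF cells (highest other 64), and the other 6 all carried part of the KO effect. In GM-CSF cells edgeR called 0 genes, which 50 of 50 splits reach by definition (highest other 306), so the count of splits says nothing there. In the real split 2016 genes had an unadjusted p under 0.05 by edgeR, and DESeq2 called 3 at an adjusted p under 0.05. For the KO effect difference, 7 of 50 reached the 1 gene of control cells (highest other 468) and 3 of 50 the 51 genes of S. aureus cells (highest other 75), and the other 6 and 2 carried part of the KO effect too. Of these splits 20, 18 and 17 (in the order of the 4, the 1 and the 51 genes) carried none of the KO effect, and each called 0 genes by edgeR. Of further splits drawn so that they carry none of it, with as many libraries exchanged in both conditions, 1 of 50 reached each of the 3 counts, and the highest others were 1, 0 and 1. The groups of such splits mix KO and WT libraries, so the KO effect itself widens their spread and can lower their counts. These splits therefore do not measure chance either. They were also chosen after the result was seen, and by the splits chosen before it chance stays open for the 3 counts. The 3 counts also change without 1 library, as given in the report.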
